A study of Mus musculus with 6 samples.

How the data were processed

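Gene expression was measured with Illumina bead arrays in mouse ectoderm over the eye at embryonic day 9.5. The 6 arrays were grouped by the genotype and tissue in the labels into 3 wild-type and 3 Pax6 knockout arrays. Per the labels' protocols, frozen embryos were sectioned at 10 µm, the ectoderm was laser-microdissected after eosin staining, and RNA of 3 embryos per genotype was pooled before triplicate samples of each pool were amplified to cDNA and biotin-labelled. The strain background was mixed.

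The deposited intensity values are mean bead signals per probe on a linear scale, not normalised between arrays, per the file headers and from the values. A detection p-value for each probe on each array was deposited with them, and per the file headers so were the number of beads and their standard error. The array software was GenomeStudio, per the submitters' processing notes, and its version and settings are not given in the sources used here. A second deposited table holds background-subtracted and normalised intensity values made by the authors, with the method not given in the sources used here. From its values it is linear, with 25.1% to 25.2% of values below 0 and column medians of 15.5, and each of its columns ranked the probes like the raw signals of the same array (Spearman correlation 1.0, at most 0.895 with any other array). It was used as an alternative only.

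The array held 45281 probes. A table of the platform's annotation gave 34885 of them 1 gene symbol, 18 several and 10378 none, and probes with several or none were left out of the comparison of genes. Entrez identifiers matched the RefSeq gene table of the GRCm38.p6 assembly for 34807 probes, which was used for gene names and for the order of genes along chromosomes, with no coordinates. Probe positions within transcripts were not used here.

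Values were computed with R 4.3.3 and limma 3.58.1. Background was corrected with the normexp model of the function nec, which took the background from the detection p-values because control probes were not used here, with an offset of 16. Arrays were then quantile-normalised and log2-transformed. Probes with a detection p-value under 0.01 on at least 3 of the 6 arrays were kept, and each gene was represented by its kept probe with the highest mean over the 6 arrays, which left 9190 genes. Of 301 genes past the threshold, 115 had another kept probe, and 163 of these 187 other probes had the same sign, 52 of them also past the threshold when every kept probe was tested.

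Knockout and wild type were compared with limma's linear model, moderated with an intensity trend (4 residual degrees of freedom per gene), and p-values were adjusted by the Benjamini-Hochberg method. A gene was called at an adjusted p under 0.05. All p-values are two-sided. Changes are knockout minus wild type on the log2 scale, with the moderated standard error (SE). A gene not detected on any array of 1 group has only a bound there, and its change is given as "at least N-fold": the mean of the brighter group against the mean of, per array, the higher of the lowest detected signal and the probe's own value. Because the arrays of a genotype came from 1 RNA pool, the spread is that of amplification and array. The p-values compare 2 pools and are too small with respect to embryos. The number of arrays limits the precision. Between 16242 and 17735 probes were detected per array (35.9% to 39.2%), with a median of 44 or 45 beads per probe.

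Before the data were examined, 27 gene lists were fixed, with 541 entries of which 493 were on the array. They covered lens determination, crystallins and lens fibre genes, Wnt antagonists, Wnt targets, BMP and TGF-beta signalling, FGF targets, Notch, extracellular matrix, cell shape, cadherins and adhesion, surface ectoderm, olfactory placode, optic vesicle, neural tube, mesenchyme, endothelium, erythroid cells, macrophages, proliferation, cell cycle exit, apoptosis, stress and early response, hypoxia and glycolysis, endoplasmic reticulum (ER) stress, ribosomal proteins, oxidative phosphorylation and sex-linked genes. Lists were compared with the other genes by camera with a preset correlation of 0.01, and the 26 with at least 3 tested genes were adjusted together. Calls within a list are given over all genes tested and adjusted over the list alone.

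The genes named in the text were also set by a rule before the data were examined. They are Pax6, the 10 genes with the highest and the 10 with the lowest change among those called, detected on all 6 arrays and with groups that did not overlap, and up to 6 called genes per direction detected in 1 group only. From each list come up to 4 called members with the largest change (every called member of the lens determination and crystallin lists, every tested sex-linked gene), or up to 2 of the highest members where none was called. Clone and provisional gene names were passed over. Other genes are marked as set for a test of an explanation or as chosen after their values were seen.

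Arrays lay on 2 slides: slide 1 held wild type 1 and 3 and knockout 2 and 3, and slide 2 held wild type 2 and knockout 1. Alternatives were no background correction, an offset of 50, median scaling, the authors' values, no detection filter, detection on all 6 arrays, testing every probe, moderation without a trend or robustly, array weights, the slide as a block, slide 1 only, the replicate number as a block, a test against a 1.2-fold change, leaving out each array in turn, and for the lists camera with an estimated correlation, the rotation test fry, and lists without shared members. Leaving out the genes of chromosomes X and Y was added after the data were seen.

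The procedure was tested on data simulated 5 times from the arrays' own levels and spread, with 9827 genes tested on average. Each time 200 genes were changed by 1 or 2 on the log2 scale, and the genes of the shifted lists by 0.7. The procedure found 62.1% of tested genes lowered by 2 on the log2 scale, 29.9% of those lowered by 1, 38.3% of those raised by 1 and 80.4% of those raised by 2. Of 570 calls 23 were false, with the genes of the shifted lists counted as truly changed. Camera found 20 of 20 lists shifted by 0.7 on the log2 scale with the preset correlation and 16 with an estimated one, and called 0 of 110 unshifted lists with either. The simulated genes varied independently of one another, so these rates do not test camera on lists whose members vary together. Apart from the set changes the simulated genotypes did not differ, so the false calls do not cover differences between pools or embryos. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.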

Results

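Transcripts were profiled on 6 Illumina bead arrays from mouse ectoderm over the eye at embryonic day 9.5, the stage at which surface ectoderm touching the optic vesicle thickens into the lens placode. Wild-type tissue is labelled lens placode (3 arrays) and Pax6-/- tissue surface ectoderm (3 arrays). Each genotype was represented by 1 RNA pool of 3 embryos, hybridised in triplicate, so every p-value given here compares 2 pools and is too small with respect to embryos. Between 16242 and 17735 of 45281 probes were detected per array. Correlations of log2 values over genes were 0.947 to 0.954 within a genotype and 0.925 to 0.936 between genotypes. The first principal component, with 36.1% of the variance, separated the genotypes.

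The comparison asked which genes change in eye ectoderm when Pax6, a paired-box and homeodomain transcription factor required for eye formation, is lost. Knockout ectoderm had lower levels of Pax6 itself, of the lens regulators Prox1, Maf, Otx1, Mab21l1 and Sox2, of the crystallins Cryge and Crybb3, of the retinoic acid-synthesising enzyme Aldh1a3, and of the matrix genes Tnc, Has2 and Col13a1. It had higher levels of the basal keratin Krt14, the growth factor Bmp4, the forkhead gene Foxi2 and the zinc-finger gene Zic1. Transcripts of 3 globins were also higher in the knockout pool, and more blood cells in its capture could not be excluded as the source. Zic1 is also a gene of the neural tube list, and more neural tissue in the knockout capture was not tested. The pools also differed in sex-linked transcripts, and the region dissected cannot be separated from genotype. Of 9190 genes tested, 139 were higher and 162 lower in the knockout (limma, adjusted p under 0.05), of which 83 and 110 differed at least 2-fold. At an unadjusted p under 0.05, 1556 genes differed. The arrays of the genotypes did not overlap for all 301 called genes, as for 22.8% of all tested genes, where chance gives 10%.

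Across all tested genes, the changes on slide 1 and on slide 2 correlated at 0.388. With the slide as a block 126 genes were higher and 150 lower, and on slide 1 alone, with 2 arrays per genotype, 28 and 41. The counts fell to 107 higher and 103 lower genes without wild-type array 1, 90 and 83 without wild-type array 2, 91 and 95 without wild-type array 3, 73 and 102 without knockout array 1, 59 and 91 without knockout array 2, and 89 and 119 without knockout array 3. With median scaling in place of quantile normalisation 88 genes were higher and 347 lower, so that 20.2% of calls were higher against 46.2%, and the median of all genes moved from -0.012 to -0.192. That scaling set equal the medians of all 45281 probes. Only 35.9% to 39.2% of them were detected per array, so the level it aligned lay below detection. Of 69 called named genes, 35 missed the threshold on slide 1 alone, 21 without an intensity trend, 19 in a test against 1.2-fold, 10 with no detection filter, 5 with median scaling and 3 with the slide as a block. The losses given below for single genes are mostly those with 1 array left out.

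**Figure D1:**
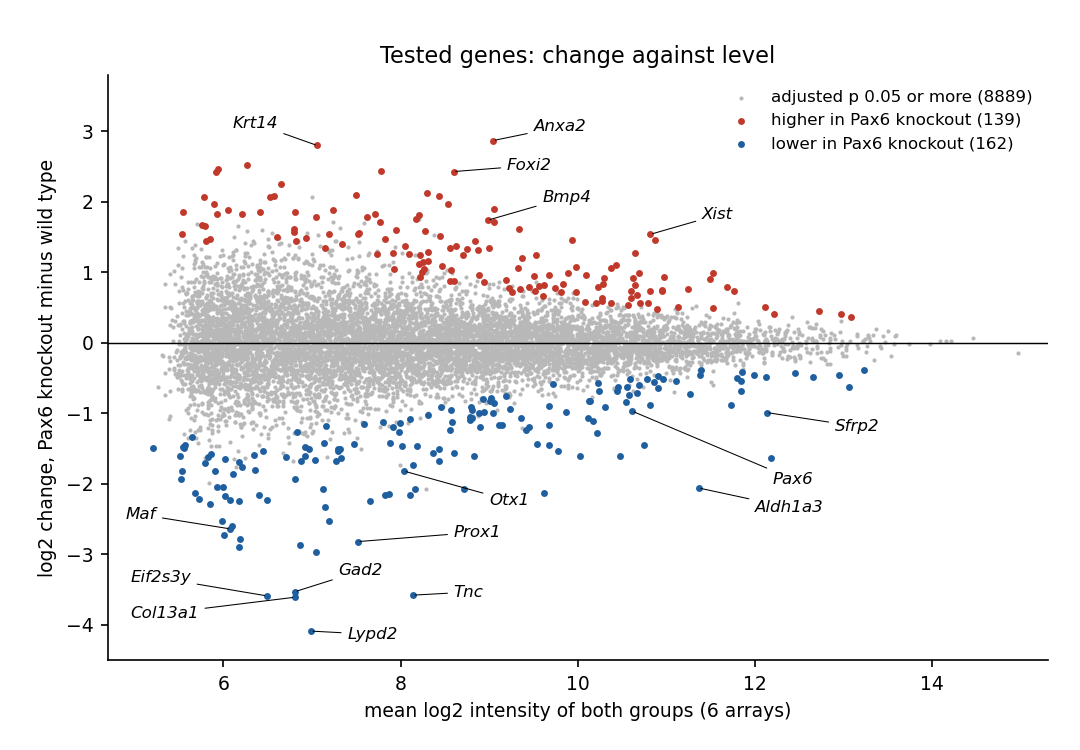
Change between genotypes (log2, Pax6 knockout minus wild type) against mean log2 intensity of the 6 arrays for each of 9190 tested genes. Red points are the 139 genes higher and blue points the 162 genes lower in the knockout at an adjusted p under 0.05, and the smallest changes that passed lay at high intensity.

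Pax6 transcript was detected on every array, at a log2 intensity of 11.10 ± 0.19 (SD, n = 3) in wild type and 10.13 ± 0.11 (SD, n = 3) in knockout. The change was -0.97 (SE 0.13, limma adjusted p = 0.00237), or 1.95-fold lower, and a second Pax6 probe gave -1.11 (SE 0.13, adjusted p = 0.000926 when every kept probe was tested). With the slide as a block the change was -0.97 (adjusted p = 0.00443), on slide 1 alone -0.93 (adjusted p = 0.0543), and between the 2 arrays of slide 2 -1.04, with no test. The labels do not state which part of the gene was deleted, so these probes do not check the genotype.

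Lens regulators went both ways. Of 16 tested genes of the lens determination list, 5 fell, 2 rose and 9 did not pass (6 lower and 3 higher adjusted over the list alone). Prox1, a homeobox factor required for lens fibre elongation, fell by 2.82 on the log2 scale (SE 0.34, adjusted p = 0.00134) and was detected on 2 of the 3 knockout arrays. Maf, a leucine-zipper activator of crystallin genes, was not detected on any knockout array and was at least 3.18-fold lower (adjusted p = 0.00115). Otx1, a homeobox gene of the anterior head, fell by 1.82 (SE 0.28) and Mab21l1, which is required for lens vesicle formation, by 1.45 (SE 0.14). Sox2, which acts with Pax6 on lens enhancers, fell by 0.95 (SE 0.20, adjusted p = 0.0271). Sox11, a SoxC family factor, rose by 0.45 (SE 0.07, adjusted p = 0.00591) and the cofactor Dach1 by 1.78 (SE 0.40, adjusted p = 0.0371). Further Dach1 probes stood at 0.79, 1.48 and 1.55 (limma adjusted p 0.0777 to 0.452 when every kept probe was tested). The list as a whole did not differ from other genes by camera (median -0.09, adjusted p = 0.243, and adjusted p = 0.444 with an estimated correlation), although it did without the members shared with other lists (adjusted p = 0.0425). The tested members so left out, Lhx2 (1.18, SE 0.37) and Eya1 (0.12, SE 0.10), both lay above 0. They were named after their values were seen. The call of Sox2 was lost without wild-type array 1, 2 or 3 or knockout array 1 or 3 (adjusted p up to 0.0958), and that of Dach1 without wild-type array 2 or 3 or knockout array 2 or 3 (up to 0.141). Sox11 missed the threshold with median scaling, without an intensity trend, on slide 1 alone and in a test against 1.2-fold (change down to 0.18, adjusted p up to 0.404).

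Crystallins and other lens fibre genes were called as a group by camera with the preset correlation of 0.01 (adjusted p = 0.00125). They were not called with an estimated one (adjusted p = 0.2), although the estimate, -0.036, was below the preset value. Of 9 tested genes 2 fell and 7 did not pass (3 lower adjusted over the list alone). All 9 had negative changes, with a median of -0.92 (-0.69 with genes not detected in 1 genotype at their bound), which was -0.15 with no detection filter, -0.29 without background correction and -0.53 with an offset of 50. Cryge, a gamma-crystallin, was at least 3.59-fold lower (adjusted p = 0.00092) and Crybb3, a beta-crystallin, at least 1.63-fold lower (adjusted p = 0.014), neither being detected on any knockout array. The call of Crybb3 was lost without wild-type array 1 or 2 or knockout array 1 or 2 (adjusted p up to 0.0648). With the slide as a block the group had an adjusted p = 0.00117, and its median was -0.76 on slide 1 (adjusted p = 0.00472) and -1.34 on slide 2.

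Single genes passed in the Wnt antagonist, BMP and FGF lists, and 0 genes in the Wnt target and Notch lists. In the Wnt antagonist list 2 of 10 genes fell and 0 rose (2 lower and 3 higher adjusted over the list alone). Dkk3, of the Dickkopf family, fell by 1.60 (SE 0.14, adjusted p = 0.000208) and Sfrp2, a secreted Frizzled-related protein, by 0.99 (SE 0.08, adjusted p = 0.000139). That list's median (0.13) and mean (0.01) were above 0 while camera's direction was down (adjusted p = 0.892), and with median scaling the median was -0.03. For 8 Wnt targets limma called 0 genes over all genes and 0 adjusted over the list alone, with 2 at an unadjusted p under 0.05. Their median was 0.33 (camera adjusted p = 0.321), with Ccnd1 at -0.23 (SE 0.10) and Apcdd1 at 0.35 (SE 0.36). Bmp4 rose by 1.74 (SE 0.20, adjusted p = 0.00098) and was the only called gene of 15 in the BMP and TGF-beta list over all genes or adjusted over the list alone (median 0.02, or -0.21 with median scaling; camera adjusted p = 0.462). In the FGF target list 2 of 12 genes fell and 0 rose (3 lower and 2 higher adjusted over the list alone, camera adjusted p = 0.345). Dusp6, an ERK phosphatase induced by FGF signalling, fell by 0.69 (SE 0.11), although a dim further probe for it stood at 1.40 (adjusted p = 0.0636) and the call was lost without an intensity trend and in the test against 1.2-fold (adjusted p up to 0.115). Etv1, an ETS factor, fell by 1.46 (SE 0.31), while a dim further probe for it stood at -0.01 (adjusted p = 0.995). The call of Etv1 was lost without wild-type array 1, 2 or 3 or knockout array 1 or 2 (adjusted p up to 0.087). For 8 Notch genes limma called 0, also adjusted over the list alone, with 3 at an unadjusted p under 0.05 (median 0.48, camera adjusted p = 0.326), and Hey1 stood at 0.66 (SE 0.21) and Jag1 at -0.58 (SE 0.20). The Notch median was 0.30 to 0.67 with 1 array left out.

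Matrix, cell-shape and adhesion genes that passed the test were all lower. Of 25 extracellular matrix genes 3 fell and 0 rose (5 lower and 4 higher adjusted over the list alone, camera adjusted p = 0.284). Tnc, which encodes tenascin-C, fell by 3.58 (SE 0.46, adjusted p = 0.00173) and was detected on 2 of 3 knockout arrays. Col13a1, a transmembrane collagen, was not detected in the knockout and at least 7.32-fold lower, and the hyaluronan synthase Has2 fell by 1.57 (SE 0.23). Fn1, which encodes fibronectin and was named after its value was seen, did not pass (-0.69, SE 0.18, adjusted p = 0.0599). Of 17 cell-shape genes 2 fell and 0 rose, also adjusted over the list alone (median -0.20, camera adjusted p = 0.221). The actin crosslinker Actn1 fell by 0.96 (SE 0.19) and Rnd3 by 0.46 (SE 0.08, adjusted p = 0.013). The Rnd3 call was lost without wild-type array 2 or 3 or knockout array 2 (adjusted p up to 0.0538). It was also lost without an intensity trend, on slide 1 alone and in the test against 1.2-fold (up to 0.369). Of 17 cadherin and adhesion genes only Cdh4 fell, by 1.68 (SE 0.38), against 2 lower and 1 higher adjusted over the list alone (camera adjusted p = 0.345). The calls were lost for Actn1 without wild-type array 1, 2 or 3 or knockout array 1 or 2 (adjusted p up to 0.0758) and for Cdh4 without wild-type array 2 or 3 or knockout array 1, 2 or 3 (up to 0.125).

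**Figure D2:**
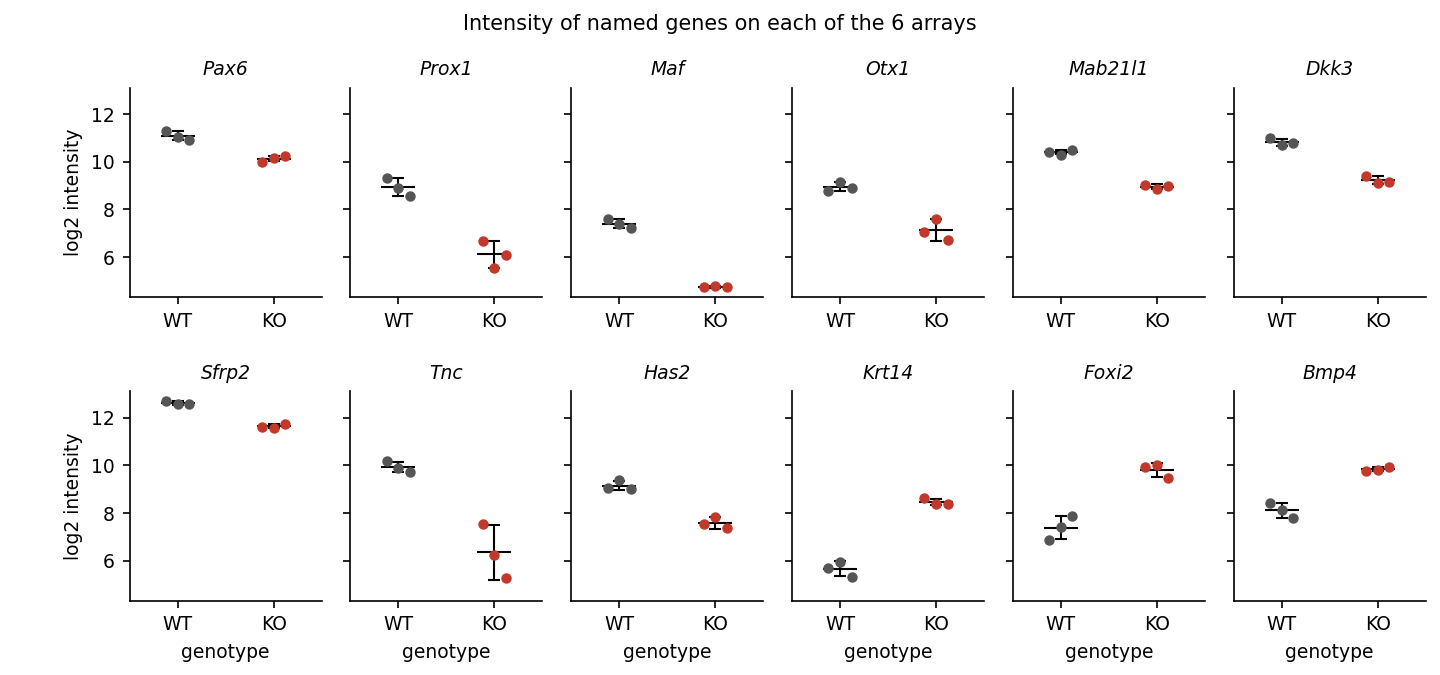
Log2 intensity of named genes on each of the 3 wild-type and 3 Pax6 knockout arrays; points are arrays, long bars means and whiskers 1 SD. The genotypes did not overlap for any of these genes, and Tnc had the widest spread, with an SD of 1.14 in the knockout.

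Epidermal genes rose in part. In the surface ectoderm list 4 of 18 genes rose and 1 fell (4 higher and 2 lower adjusted over the list alone, median 0.07, or -0.17 with median scaling, camera adjusted p = 0.329, and 0.0121 without members shared with other lists). With all members it had an adjusted p = 0.521 with an estimated correlation. The tested shared members, Dlx3, Epcam (-0.33, SE 0.13) and Cdh1 (-0.22, SE 0.06), all lay below 0. Epcam and Cdh1 were named after their values were seen. Krt14, a keratin of basal epidermis, rose by 2.80 (SE 0.30, adjusted p = 0.000704) and was detected on 2 of 3 wild-type arrays. Perp, a desmosomal protein, rose by 1.26 (SE 0.25) and Trp63, the p63 regulator of stratified epithelium, by 0.77 (SE 0.17). The other gene that rose, Tfap2b, was named after its values were seen (0.75, SE 0.11). Dlx3, a homeobox gene of epidermis and placodes, fell by 0.88 (SE 0.12) and was also the only called gene of 6 in the olfactory placode list (1 higher and 1 lower adjusted over the list alone, camera adjusted p = 0.999). The calls were lost for Perp without wild-type array 1 or knockout array 1, 2 or 3 (adjusted p up to 0.0801) and for Trp63 without wild-type array 1 or 2 or knockout array 1, 2 or 3 (up to 0.129) and with median scaling.

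Across all genes, the highest changes among genes detected on all arrays were those of Anxa2, a calcium-dependent membrane-binding protein (2.87, SE 0.34), and Foxi2, a forkhead gene of cranial ectoderm (2.43, SE 0.27). They were followed by the chondroitin sulfotransferase Chst15 (2.12, SE 0.35), the tight-junction protein Cldn11 (2.09, SE 0.23), the noncoding RNA Miat (1.97, SE 0.36), the laminin receptor Bcam (1.90, SE 0.21), Emp1 (1.89, SE 0.32), Zic1 (1.83, SE 0.28), the septin gene Septin3 (1.82, SE 0.32) and the ciliary kinesin Kif7 (1.79, SE 0.28), with adjusted p from 0.000846 to 0.0135. A further Chst15 probe detected on all 6 arrays stood at 0.49 (adjusted p = 0.486), and the Chst15 call was lost without an intensity trend and on slide 1 alone (adjusted p up to 0.0563). The call of Miat was lost without knockout array 1 or 2 (adjusted p up to 0.0726) and that of Septin3 without knockout array 2 (0.0556). Another Septin3 probe rose by 2.11 (adjusted p = 0.00439), while dimmer ones stood at 0.36, 0.26 and 0.06 (adjusted p 0.716 to 0.963). Bhlhe40, a helix-loop-helix repressor, was not detected in wild type and was at least 2.95-fold higher, as were Tnik (2.63-fold), the chemokine receptor Cxcr6 (2.42-fold), the T-box gene Tbx20 (2.32-fold), Dtx4 (1.90-fold) and the forkhead gene Foxq1 (1.82-fold). The calls were lost whichever array was left out for Dtx4 (adjusted p up to 0.1), without wild-type array 1, 2 or 3 or knockout array 2 or 3 for Foxq1 (up to 0.0875), and without knockout array 1 or 3 for Tnik (up to 0.0585).

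Among the lowest were the retinaldehyde dehydrogenase Aldh1a3, at -2.06 (SE 0.12, adjusted p = 9.89e-06), Steap1 (-2.33, SE 0.29), Rai2 (-2.24, SE 0.26), the SRF coactivator Myocd (-2.16, SE 0.25), Egfem1 (-2.16, SE 0.27), the glutaredoxin Glrx (-2.15, SE 0.25), the vesicle-release factor Cadps2 (-2.13, SE 0.17), Phlda1 (-2.08, SE 0.31) and the collagen prolyl hydroxylase P3h2 (-2.07, SE 0.24), with adjusted p of at most 0.0044. Lypd2 was not detected on any knockout array and was at least 9.84-fold lower, the GABA-synthesising enzyme Gad2 at least 7.14-fold and the nuclear receptor gene Nr1h5 at least 3.70-fold. Each of these calls held when any 1 array was left out. A further Glrx probe stood at -1.19 (adjusted p = 0.18) and a further Nr1h5 probe at -1.38 (adjusted p = 0.0812). In all, 32 lower genes were undetected on every knockout array by the probe used (31 by any probe of the gene) and 12 higher genes on every wild-type array.

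Some markers of neighbouring tissues also differed between the pools, whereas 0 tested endothelial and macrophage genes passed. All 5 tested erythroid genes lay above 0, with a median of 1.11 (0.14 with no detection filter), and 3 rose (5 adjusted over the list alone): Hba-a1 by 1.58 (SE 0.21), Hbb-bh1 by 0.92 (SE 0.14) and Hbb-y by 0.92 (SE 0.14). The calls of Hbb-bh1 and Hbb-y were lost without an intensity trend and on slide 1 alone (adjusted p up to 0.069 and 0.111). Camera gave an adjusted p = 1.2e-06, and an adjusted p = 0.132 with an estimated correlation. Of 14 mesenchyme genes, which had a median of 0.69 (0.30 with no detection filter, 0.34 without background correction), 3 rose and 1 fell (7 higher and 1 lower adjusted over the list alone; camera adjusted p = 0.00518, and an adjusted p = 0.219 with an estimated correlation). The cartilage and neural crest regulator Sox9 rose by 0.74 (SE 0.10), the homeobox gene Alx4 by 0.99 (SE 0.21) and the collagen gene Col3a1 by 0.94 (SE 0.22), whereas the growth factor receptor gene Pdgfra fell by 1.23 (SE 0.15). Dimmer probes stood at 1.27 for Sox9, 0.89 and 1.5 for Alx4 and 0.44 for Col3a1 (limma adjusted p 0.103 to 0.686). Of 10 optic vesicle genes, with a median of 1.10 (0.93 with bounds, 0.17 with no detection filter, 0.66 with detection on all 6 arrays, 0.46 without background correction), 9 lay at or above 0 and the only called one, Aldh1a3, fell (6 higher and 1 lower adjusted over the list alone). Camera's direction for them was up (adjusted p = 0.0238, and an adjusted p = 0.444 with an estimated correlation). Zic1 was the only called gene of 5 in the neural tube list (2 higher adjusted over the list alone, camera adjusted p = 0.284), and the list's median of 0.09 was -0.06 with median scaling, -0.08 to 0.58 with 1 array left out, 0.96 on slide 1 and 0.34 on slide 2. For 4 endothelial genes limma called 0, also adjusted over the list alone, with 0 at an unadjusted p under 0.05, and their median (-0.16) and mean (-0.02) lay below 0 while camera's direction was up (adjusted p = 0.999). Egfl7 stood at -0.25 (SE 0.26) and Cldn5 at 0.68 (SE 0.36). The macrophage genes Laptm5 (0.32, SE 0.34) and Aif1 (1.08, SE 0.68) were too few for camera, and limma called 0 of them over all genes or the list alone, with 0 at an unadjusted p under 0.05.

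Within slides, the erythroid median was 1.34 on slide 1 (adjusted p = 8.71e-06) and 1.09 on slide 2, the mesenchyme median 0.76 (adjusted p = 0.0178) and 0.70, and the optic vesicle median 0.89 (adjusted p = 0.105) and 0.92. With the slide as a block the adjusted p was 2.15e-06, 0.00631 and 0.0185. The optic vesicle call was lost without wild-type array 1 (adjusted p = 0.0619), knockout array 1 (0.101) or knockout array 3 (0.0689), with no detection filter (0.11), without members shared with other lists (0.119) and with detection on all 6 arrays (0.553). The last also ended the mesenchyme call (0.0732). The calls were lost for Alx4 without wild-type array 2 or 3 or knockout array 1 or 2 (adjusted p up to 0.101) and for Col3a1 whichever array was left out (up to 0.136). Both calls were also lost with median scaling, with no detection filter, on slide 1 alone and in the test against 1.2-fold, that of Alx4 without an intensity trend, and that of Col3a1 with the slide or the replicate number as a block (up to 0.232 for Alx4 and 0.257 for Col3a1). In all, camera called 4 of 26 lists, 0 of them with an estimated correlation (smallest adjusted p = 0.132), and fry, which asks only whether a list's genes move on balance one way, called 12. The estimated correlation exceeded the preset 0.01 for the optic vesicle list (0.077). It was lower for the crystallin (-0.036), erythroid (-0.094) and mesenchyme (0.008) lists, so a higher correlation is not what ended their calls.

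**Figure D3:**
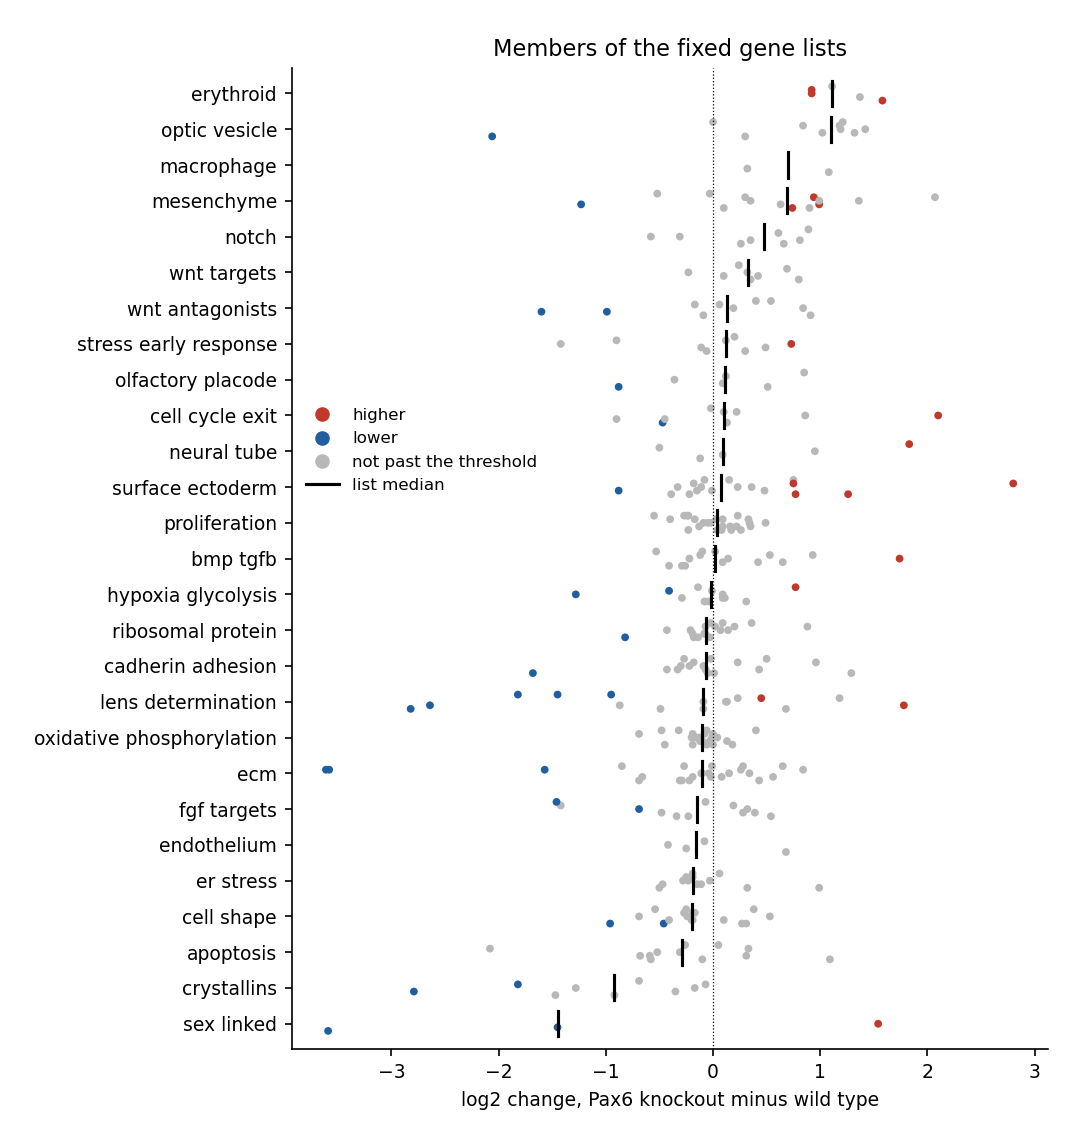
Change between genotypes (log2, Pax6 knockout minus wild type) of every tested member of the 27 gene lists, ordered by list median (black bar). Red and blue points passed the test over all genes. The crystallin median is -0.92 and the erythroid median 1.11.

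Sex-linked genes differed between the pools. By the probes used, Eif2s3y and Kdm5d, which lie on chromosome Y, were detected on every wild-type array and on 0 of 3 knockout arrays, at least 5.86-fold and 1.47-fold lower (adjusted p = 0.000139 and 0.0345). A dimmer Eif2s3y probe was detected on 2 of 3 knockout arrays (-1.15, adjusted p = 0.11), so the bound holds for the brighter probe only. The X-inactivation transcript Xist rose by 1.54 (SE 0.13, adjusted p = 0.000152). Further Xist probes rose by 1.40, 2.57 and 2.64 (limma adjusted p at most 0.00105 when every kept probe was tested). All 3 tested genes of this list were thus called (2 lower and 1 higher, also adjusted over the list alone; camera adjusted p = 0.345, median -1.45, or -0.55 with bounds). The call of Kdm5d was lost whichever array was left out (adjusted p up to 0.109). It was also lost on slide 1 alone, with the slide or the replicate number as a block, and in the test against 1.2-fold (up to 0.22). Without the genes of chromosomes X and Y, an alternative chosen after the data were seen, 131 genes were higher and 156 lower.

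No shift was detected by camera in cell cycle or cell death genes as groups. Of 25 proliferation genes limma called 0, also adjusted over the list alone, with 4 at an unadjusted p under 0.05, and Mcm4 stood at -0.27 (SE 0.07, adjusted p = 0.0637) and Mcm5 at 0.04 (SE 0.07). Their median was 0.04 and mean 0.02 while camera's direction was down (adjusted p = 0.999), and the median was -0.20 with median scaling. Dimmer Mcm4 probes, detected on every array, stood at 0.48 and 0.65 (limma adjusted p = 0.491 and 0.381). Of 9 cell cycle exit genes Gadd45g, a stress-induced growth inhibitor, rose by 2.10 (SE 0.48) and the antiproliferative gene Btg1 fell by 0.47 (SE 0.10), the same 1 and 1 adjusted over the list alone (median 0.10, or -0.06 with median scaling; camera adjusted p = 0.999). Of 12 apoptosis genes limma called 0, also adjusted over the list alone, with 3 at an unadjusted p under 0.05 (median -0.29, camera adjusted p = 0.359), and Bbc3 stood at -0.68 (SE 0.25) and Mdm2 at 0.05 (SE 0.11). The calls were lost for Gadd45g without wild-type array 1 or knockout array 1, 2 or 3 (adjusted p up to 0.157) and for Btg1 whichever array was left out (up to 0.0972). That of Gadd45g was also lost with the slide as a block and with the authors' values, among others. Its change was 2.59 on slide 1 and 1.10 on slide 2. A dimmer Btg1 probe stood at -0.22 (limma adjusted p = 0.622).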

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

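Probes with no single gene name were tested outside the comparison of genes, a test that was not among the planned comparisons. Among 2786 such probes detected on at least 3 arrays, 45 were higher and 35 lower in the knockout (limma, adjusted p under 0.05), of which 26 and 28 differed at least 2-fold. They drew attention because they carry a difference between the genotypes in probes that no gene result uses. Of the 9190 genes tested 3.28% were called, and the share among these probes was not above that. The smallest adjusted p among them was 9.9e-06, for a probe with a change of 1.97 (SE 0.10). They were not matched to genes here, and no explanation was tested.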

How the results depend on the processing

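Leaving out the genes of chromosomes X and Y was chosen after the data were seen; the other alternatives were fixed before. The 69 called named genes gave 1360 values under the alternatives, of which 1165 kept direction and side of the threshold, 195 kept the direction only and 0 turned. Of these genes 30 kept their call in every alternative that gave them a value, 10 of them having no value with detection on all 6 arrays. The counts of genes higher and lower were 88 and 347 with median scaling, 89 and 107 with no detection filter (19057 genes tested), 72 and 104 without an intensity trend, 28 and 41 on slide 1 alone (4 arrays), and 58 and 74 in a test against 1.2-fold. Genes at least 2-fold higher and lower numbered 31 and 39 without background correction, 22 and 34 on slide 1 alone, and 44 and 68 in the test against 1.2-fold. The 2-fold lower genes numbered 170 with median scaling, 72 with no filter and 66 with detection on all 6 arrays. That filter removes genes missing from 1 genotype, left too few crystallins for a value, and left 1 list with a shift, against 4. Over all tested genes 0 lists shifted under an estimated correlation and 12 with fry. Lists were not tested again against 1.2-fold, since camera does not use a fold limit. With 1 array left out, 59 to 107 genes were higher, 83 to 119 lower, 36 to 77 at least 2-fold higher and 61 to 81 at least 2-fold lower, and 3 to 4 lists shifted. Pax6 missed the threshold on slide 1 alone (-0.93, adjusted p = 0.0543) and passed it elsewhere. Median scaling, which aligned a level below detection, put the median of all genes at -0.192. With it the medians of 8 lists turned negative, among them surface ectoderm (-0.17), BMP and TGF-beta (-0.21) and neural tube (-0.06). With 1 array left out the medians of some lists spanned 0: -0.08 to 0.58 for neural tube, -0.12 to 0.17 for cell cycle exit, -0.08 to 0.12 for BMP and TGF-beta and -0.20 to 0.04 for endothelium. Except where a construction is named, the cause was not tested.

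With the replicate number as a block 81 genes were higher and 101 lower, 52 and 74 at least 2-fold, and 4 lists shifted. The numbers do not pair the arrays: deviations of same-numbered arrays correlated at -0.026, -0.024 and -0.002, and 0 of 6 arrays correlated best with its own number. Dim genes limit all counts: 32 lower genes have only a bound in the knockout and 12 higher genes only a bound in wild type.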

Other observations

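Apart from the splits of the arrays, the tests of explanations in this part were chosen after the pattern they address was seen. Their bounds were set before their own values were seen, and what was altered afterwards is named with the result. Housekeeping and metabolic genes held a few single changes. Of 12 hypoxia and glycolysis genes 1 rose and 2 fell, also adjusted over the list alone (median -0.02, camera adjusted p = 0.892). The oxygen-sensing prolyl hydroxylase Egln3 fell by 1.28 (SE 0.18, adjusted p = 0.00316) and the glucose transporter Slc2a1 by 0.41 (SE 0.09), while the related transporter Slc2a3 rose by 0.77 (SE 0.11, adjusted p = 0.0035). Dimmer Egln3 probes stood at -1.02 and -0.41 (limma adjusted p = 0.16 and 0.648 when every kept probe was tested). The call of Slc2a1 was lost without wild-type array 1, 2 or 3 or knockout array 2 or 3 (adjusted p up to 0.129). Of 9 stress and early response genes the zinc-finger gene Klf6 alone passed, rising by 0.73 (SE 0.10, adjusted p = 0.00293, but down to 0.47 and an adjusted p up to 0.0722 with median scaling, without an intensity trend or on slide 1 alone), against 1 higher and 1 lower adjusted over the list alone (median 0.12, or -0.13 with median scaling, mean -0.07, camera direction up, adjusted p = 0.532).

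Of 19 ribosomal protein genes Rplp0 alone passed, falling by 0.82 (SE 0.14), against 1 higher and 1 lower adjusted over the list alone (median -0.07, camera adjusted p = 0.743, and 0.0152 with median scaling). Under quantile normalisation the list had an adjusted p = 0.744 by camera with an estimated correlation. A dimmer Rplp0 probe stood at -0.59 (limma adjusted p = 0.275). For 13 ER stress genes limma called 0, also adjusted over the list alone, with 3 at an unadjusted p under 0.05 (median -0.19, camera adjusted p = 0.284), and Hspa5 stood at -0.25 (SE 0.08) and Hsp90b1 at -0.23 (SE 0.07). For 23 oxidative phosphorylation genes limma called 0, also adjusted over the list alone, with 3 at an unadjusted p under 0.05 (median -0.10, camera adjusted p = 0.169, and 0.00509 with median scaling), and they had an adjusted p = 0.444 with an estimated correlation under quantile normalisation. Ndufb8 stood at -0.06 (SE 0.09) and Cox6c at -0.13 (SE 0.07).

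The lower Y-linked transcripts and the higher Xist may come from fewer male embryos in the knockout pool. Of the 4 genes that escape X inactivation set for this test, 0 passed by limma: Kdm6a stood at 0.76 (SE 0.31), Eif2s3x at 0.37 (SE 0.29), Kdm5c at 0.11 (SE 0.30) and Ddx3x, the most precise, at 0.01 (SE 0.09). Their median of 0.24 (SE 0.16) was above 0 by more than its SE, the bound set for a larger share of female embryos, but by less than 2 SE. The labels give no sex, so this stays a hypothesis and the number of male embryos stays open. A dimmer Eif2s3y probe was detected on 2 of 3 knockout arrays. Its knockout mean of 5.78 lay at the lowest detected signals of those arrays (5.65 to 5.81), so it does not establish a Y-linked transcript there. Effects of sex on autosomal genes were not tested.

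The 301 called genes were set against 3 explanations. Chromosomes X and Y held 3.99% of them (12 genes) and 3.4% of tested genes (Fisher's exact p = 0.517). The wording of this explanation, the dosage of these chromosomes, was narrowed from sex in general after its value was seen. Strain variants carried with the Pax6 locus could act on nearby genes. Among the 200 nearest tested neighbours, which are 2.18% of tested genes, lay 0.667% of the called genes other than Pax6 (Fisher's exact p = 0.0692). These were Alx4 and Sema6d (-1.09, SE 0.23, named after its value was seen). For neither set was an excess of calls detected, but few tested genes lie there, so a large share was unlikely in advance. For chance, the real split of the arrays was 1 of 10 and gave 301 genes, 193 at least 2-fold, and 4 lists against at most 0 in the other splits, but 10 splits are too few for a share under 0.05, and regrouping arrays of 1 pool per genotype does not address differences between embryos. The region dissected, which carries a different name in each genotype, cannot be separated from genotype and stays open.

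The erythroid, mesenchyme and optic vesicle genes may be higher because the knockout capture held more of these neighbouring tissues, which was tested on further genes of each tissue after first tests on the list members themselves had been set aside, since those values had been seen (all 5 erythroid members above 0; Pdgfra and Aldh1a3 below 0 by over 2 SE). The median of 14 further mesenchyme genes was 0.33 (SE 0.23), with Igf1 higher (1.48, SE 0.27) and Cxcl12 lower (-1.43, SE 0.20), and that of 4 further optic vesicle genes 0.70 (SE 0.37), with Foxd1 higher (1.49, SE 0.29; these 3 were named after their values were seen); both leave the explanation open. The median of 3 further erythroid genes was -0.23 (SE 0.54), which met the bound set against blood cells, but 2 of the 3 lay within 1 log2 unit of the lowest detected signal and can exclude nothing, a condition added after the value was seen. The brighter one, Car2, stood at -1.36 (SE 0.36, adjusted p = 0.0728). This value is opposite to more blood cells but of a single gene, whose expression in other captured cells was not tested. Of the list members, 12 of 14 mesenchyme, 6 of 10 optic vesicle and 4 of 5 erythroid genes were also detected on every wild-type array, and a change within the ectoderm was not tested.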
